A study of Mus musculus with 8 samples.

How the data were processed

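Brain tissue of neonatal C57BL/6 mice was measured by RNA-seq in 8 libraries, 4 from control neonates of naturally mated wild-type parents and 4 from ICSI-F2 neonates. ICSI, intracytoplasmic sperm injection, places a sperm directly in the egg. The ICSI-F2 animals were males whose fathers were born after ICSI and then mated naturally, and the labels do not give the sex of the controls. Groups were taken from the sample titles, and replicates were numbered in the order of deposition, so a number does not pair a control with an ICSI-F2 library. The sample codes also carry a letter, A for control replicates 1 and 2, D for control replicates 3 and 4, F for ICSI-F2 replicates 1 and 2 and G for ICSI-F2 replicates 3 and 4. The meaning of the letter is not given in the sources used here, and each letter lies inside a single group. Within the groups, pairs of the same letter were more alike than other pairs. Correlations of their log2 CPM, less the group mean of each gene, were -0.27 to -0.14, against -0.49 to -0.35 for other pairs. The consensus correlation within letters was 0.028. Libraries of the same letter may thus not be independent, whatever the letter marks, and the p-values measure only the spread between these libraries.

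Per the submitters' processing notes, the authors used bcl2fastq 2.20, cutadapt 3.4, HISAT2 2.2.1 and HTSeq 2.0.2 with the mouse build mm10. Per the labels, single reads of 76 bases were sequenced from stranded mRNA libraries, and the kit is named differently in the series text and in the sample protocols. The deposited values are raw read counts per gene, 1 column per library, not normalized and not pooled. The gene annotation release and the strand setting of the counting are not given in the sources used here, so counts of overlapping genes on opposite strands are uncertain. Near-identical genes, such as the globin pair Hba-a1 and Hba-a2, are uncertain too. Gene identifiers were looked up in GENCODE M21, on the same build, and 32158 of the 32285 identifiers (99.6%) were found there.

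Library totals were 16551511, 15163420, 15893631 and 13872777 counts in control replicates 1 to 4 and 16348777, 12968175, 13024441 and 13156327 counts in ICSI-F2 replicates 1 to 4. Of the 32285 genes, 24101 had at least 1 count, and 15565 passed edgeR's filterByExpr and were tested. The median standard error of a log2 fold change was 0.08, and the whole 95% interval lay within 1.5-fold of no change for 83.8% of tested genes. Every pair of libraries in a group differed by more than sampling noise, with a chi-square per gene of 2.43 to 7.00, so no library was counted as a duplicate. Normalized values are CPM, counts divided by the library total after scaling it with TMM factors, which lay between 0.989 and 1.01.

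The 2 groups were compared with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust dispersion, group as the only term and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. On simulated counts for 15565 genes, 200 of them changed, this test recovered 50.7% of genes changed 1.25-fold, 76.1% changed 1.5-fold and 86.4% changed 2-fold in the comparison of ICSI-F2 with control. It made 158 calls there, of which 16 (10.1%) were false. The simulated libraries were drawn independently, with no structure of tissue content or code letter. The real libraries hold such structure, so these shares may be too favourable for them. Gene lists were compared with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, over the lists with at least 5 tested genes. Camera with the correlation estimated per list, fry and an exact permutation test of the list mean were also run. In simulated null lists of 20 genes that shared a random factor, the preset correlation called 44 of 100 lists and the estimated correlation 0. Those null lists had a median estimated correlation of 0.352. The real lists past the threshold ran from 0.010 (clustered protocadherins) to 0.593 (meninges). The 44 of 100 therefore does not carry over to lists of low correlation. In lists shifted 1.15-fold with no shared factor, both called 50 of 50. How often the estimated correlation calls shifted lists whose genes do share a factor was not simulated.

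The 41 gene lists, the tests and all alternatives other than those named next were fixed before the data were examined. The runs without the code letter A libraries, without the code letter G libraries and with the exact permutation test of list means were added after the values were seen, as were the lists of posterior and liver marker genes. The lists covered cell types and regions of the neonatal brain, other tissues that a dissection can carry, cell processes, genes under epigenetic control, and checks of sex and substrain. They hold 1076 gene entries, 1064 of them in the file, and 39 lists were tested. The pituitary list and the pineal and retina list had 4 tested genes each and were left out. No gene of either list was among the genes that passed the edgeR test with all libraries and the filter on low counts.

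The genes named by rule were, in each direction, the 8 with the largest fold change at a mean of at least 1 CPM and the 6 with the smallest p among genes past the threshold, or all that passed where fewer did. Where none passed, the 6 with the smallest p were named as not passing. The 3 members of each list with the smallest p and the sex check genes Xist, Ddx3y, Kdm5d, Eif2s3y and Uty were added. Some genes the rule takes are not reported here. The neighbours of Tmem267, Rmst, Safb2, Wdfy1, Prpf38b, A430106G13Rik, Mid1, Gm21887, Gm47283, Capn11, Gh, Col1a1, Col3a1 and the Hox, Pax2 and liver genes were named after their values were seen.

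The alternatives were DESeq2 size factors or total library size in place of TMM, no filter on low counts, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom with quality weights, the code letter as a random block, counts summed per code letter, 1 surrogate variable from sva 3.50.0, an adjusted p of 0.10, a log2 fold change of at least 1, and each library left out in turn. Figures were drawn with matplotlib 3.10.9.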

Results

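Messenger RNA of whole neonatal brain tissue was counted per gene in 4 control libraries and 4 ICSI-F2 libraries, at 12968175 to 16551511 counts per library. Between 20038 and 20490 genes had at least 1 count in a library. The design sets the male grand-offspring of ICSI, reached through an ICSI-born father and natural mating, against neonates of naturally mated wild-type parents, and so asks whether brain expression differs in the generation after the ICSI-born one.

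Tmem267, which encodes a transmembrane protein, was the gene that differed between the groups, and its level in ICSI-F2 brains was 2.06 times that in controls. It stood at 9.22 ± 0.67 CPM (SD, n = 4) in control and 19.11 ± 3.67 CPM (SD, n = 4) in ICSI-F2 brains. All 4 ICSI-F2 libraries, at 16.4, 19.5, 16.4 and 24.2 CPM, lay above all 4 control libraries, at 8.31 to 9.79 CPM. The log2 fold change was 1.04 (SE 0.11, 95% interval 0.81 to 1.28), with an adjusted p of 2.04e-05 in edgeR's quasi-likelihood test over 15565 genes. Tmem267 (ENSMUSG00000074634) is a protein-coding gene on the plus strand of chromosome 13, from 119488039 to 119611059 in mm10. Its exons cover 5419 bases, of which 162 (2.99%) overlap exons of 3110070M22Rik and 181 (3.34%) exons of Gm48265, both on the minus strand. In ICSI-F2 brains those overlapping genes averaged 1.33 and 0.68 CPM.

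With all 8 libraries and the filter on low counts, the nearest tested genes did not pass the threshold, and their fold changes were of 2 kinds. Ccl28, a chemokine gene at 119623819 to 119654359 on the same strand, stood at 5.48 ± 2.31 CPM in control and 11.0 ± 1.74 CPM in ICSI-F2 brains (SD, n = 4), a log2 fold change of 0.99 with an edgeR adjusted p of 0.562. It passed with no filter on low counts (edgeR adjusted p = 0.0095) and without the code letter A libraries (log2 fold change 1.47, edgeR adjusted p = 0.0292). For 3110070M22Rik the levels were 0.64 ± 0.22 and 1.33 ± 0.31 CPM (SD, n = 4), a log2 fold change of 1.04 with an edgeR adjusted p of 0.53. In both genes all 4 ICSI-F2 libraries lay above all 4 controls. Paip1 (log2 fold change -0.02), 4833420G17Rik (0.13), Hmgcs1 (-0.0058, 0.0050 with total library size alone), Nim1k (-0.08), Zfp131 (0.05) and Nnt (-0.11, 95% interval -0.47 to 0.25) gave edgeR adjusted p of 0.705 to 0.982. Nnt encodes a mitochondrial transhydrogenase, part of which is deleted in the C57BL/6J substrain.

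**Figure D1:**
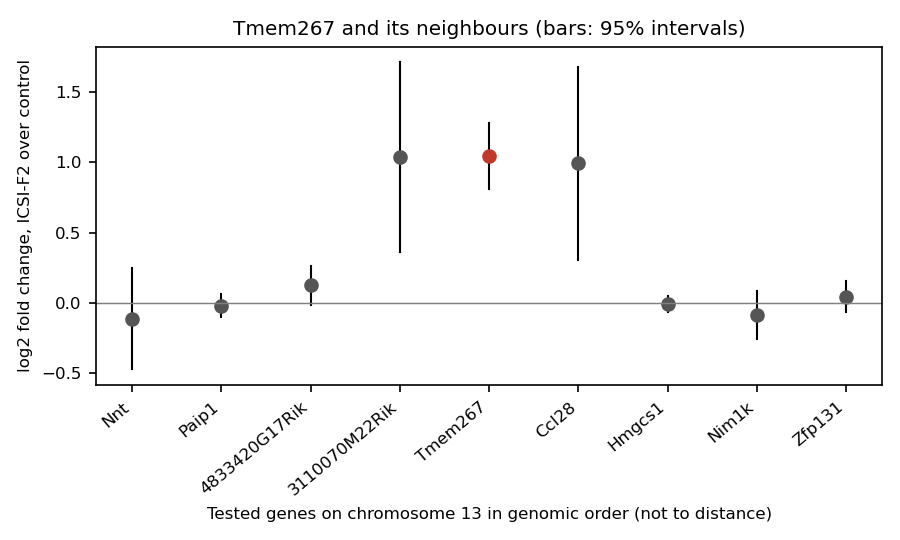
Log2 fold change (ICSI-F2 over control, y axis) of the tested genes around Tmem267 on chromosome 13 in genomic order, with 95% intervals as bars. Tmem267 lies at 1.04, 3110070M22Rik at 1.04 and Ccl28 at 0.99, and the intervals of the other 6 genes include 0.

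**Figure D2:**
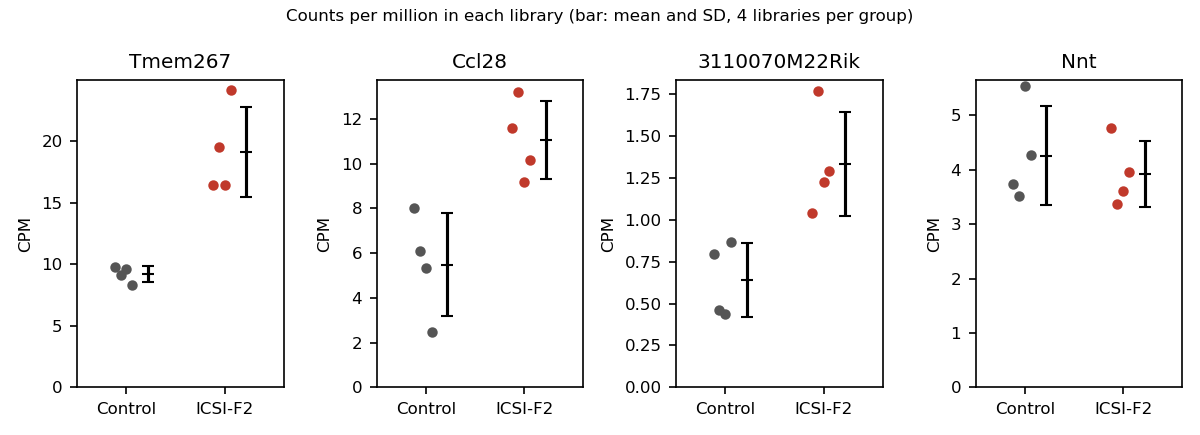
CPM (y axis) of Tmem267, Ccl28, 3110070M22Rik and Nnt in each control (grey) and ICSI-F2 (red) library, with the mean and SD of the 4 libraries per group. Tmem267 reaches 16.4 to 24.2 CPM in ICSI-F2 and 8.31 to 9.79 CPM in control libraries.

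No gene was lower in ICSI-F2 brains at an adjusted p of 0.05 in edgeR, where 525 genes were lower and 611 higher at an unadjusted p under 0.05. The counts of lower genes were 0 with DESeq2 and 0 with limma, and DESeq2 called 2 genes higher, Tmem267 and Mid1. The 6 lower genes with the smallest p did not pass with all 8 libraries and the filter on low counts. They were Arrdc3, an arrestin-domain gene (84.3 ± 3.77 CPM in control and 71.7 ± 4.56 CPM in ICSI-F2, SD, n = 4), Syt6, of the synaptotagmin family (log2 fold change -0.24), Oip5os1 (-0.13), the melanocortin receptor gene Mc4r (-0.56), Ap2b1, of the AP-2 clathrin adaptor (-0.11), and the immediate early gene Jun (-0.22). Their edgeR adjusted p lay between 0.141 and 0.427. With no filter Arrdc3, Syt6 and Oip5os1 passed in edgeR (adjusted p = 0.00139, 0.0177 and 0.0401). With 1 surrogate variable Arrdc3 and Syt6 passed (edgeR adjusted p = 0.0105 and 0.0195), and without control replicate 1 Arrdc3 did (adjusted p = 0.0367). At an adjusted p of 0.10, Rmst, a long noncoding RNA (log2 fold change 0.23), the Y-linked Eif2s3y (0.29) and Safb2 (0.32) joined Tmem267, each with an edgeR adjusted p of 0.0954. Rmst and Safb2 passed at 0.05 with no filter (edgeR adjusted p = 0.00127 and 0.000101) and without control replicate 3 (0.0448 and 0.0249), and Rmst also with 1 surrogate variable (0.0276). Without a filter on low counts edgeR called 50 genes, and without control replicate 3 it called 9. Over all tested genes the groups were apart, with no overlap of libraries, for 618 (3.97%), where chance gives 2.86%.

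Genes of the meninges, the blood and the microglia leaned toward ICSI-F2. All 22 tested genes of meningeal fibroblasts were above control, with a median log2 fold change of 0.18, among them the organic anion transporter gene Slc22a6 (0.36), Ogn (0.28) and Bgn (0.20), which encode matrix proteoglycans. The call rested on a preset correlation (limma camera, adjusted p = 2.6e-07; adjusted p = 0.516 with an estimated correlation), and without the code letter G libraries the median was -0.018. Col1a1 and Col3a1 stood at 155 and 145 CPM in ICSI-F2 replicate 3 and at 149 and 153 CPM in replicate 4, against 101 to 115 and 112 to 123 CPM in the other 6 libraries. In those 2 libraries the liver transcript Alb reached 10.4 and 20.2 CPM and Afp 2.91 and 6.23 CPM, while Alb was at most 0.077 CPM in the other 6. Of 22 microglia and macrophage genes, 17 were above control, with Lyz2 (0.51), Siglech (0.60) and Pf4 (0.42) leading (adjusted p = 0.0115 in limma camera; adjusted p = 0.533 with an estimated correlation). Relative to the control mean on the log2 scale, the microglia list stood at 0.294 and 0.270 in ICSI-F2 replicates 3 and 4, at 0.059 and 0.051 in ICSI-F2 replicates 1 and 2 and at -0.076 to 0.056 in controls. Without the code letter G libraries, those with liver transcripts, its median was 0.066, against 0.091 with all 8, and the call did not hold (limma camera adjusted p = 0.772). Of 8 blood genes, 6 were above control, led by the beta globin gene Hbb-bs, at 4.48 ± 1.36 and 7.49 ± 0.78 CPM (SD, n = 4), Alas2 of haem synthesis (0.45) and Slc4a1 (0.50). Slc4a1 stood highest in ICSI-F2 replicate 4, at 3.12 CPM against 1.07 to 1.84 CPM in the other 7 libraries, and its log2 fold change was 0.16 without that library and -0.0097 without the code letter G libraries. The blood list gave an adjusted p of 0.0186 in limma camera and an adjusted p of 0.516 with an estimated correlation. Adjusted over the list alone, 1 meningeal and 2 blood genes passed. Over all genes tested none of these lists held a gene that passed with the filter on low counts and all 8 libraries. Hbb-bs passed in edgeR with no filter (adjusted p = 0.00145) and without control replicate 3 (adjusted p = 0.0275), and Col3a1 with no filter (adjusted p = 0.00309).

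Genes of astrocytes and of the oligodendrocyte lineage leaned toward control. Of 20 astrocyte genes 16 were below control, with a median log2 fold change of -0.10, and the glutamate transporter gene Slc1a2 (-0.15), Aldh1l1 (-0.18) and Agt (-0.30) led (adjusted p = 0.00233 in limma camera; adjusted p = 0.744 with an estimated correlation). Of 17 genes of the oligodendrocyte lineage 14 were below control, led by the myelin gene Mag (-0.84), Cspg4 (-0.15) and Olig1 (-0.13), with an adjusted p of 0.00569 in limma camera and an adjusted p of 0.658 with an estimated correlation. The medians of these lists were 0.013 and 0.031 without the code letter A libraries, where the log2 fold change of Agt was 0.081. Those libraries, control replicates 1 and 2, held transcripts of posterior Hox genes, with Hoxa5 at 16.3 and 5.96 CPM and Hoxb5 at 17.7 and 7.42 CPM, against at most 0.077 CPM for either gene in the other 6. The glycine transporter gene Slc6a5 stood at 26.1 and 21.8 CPM there and at 0.684 to 6.28 CPM in the other 6. Radial glia genes (5 of 19 above control, adjusted p = 0.204 in limma camera) did not pass, with Nes at 0.14, Fabp7 at 0.08 and Ttyh1 at -0.15 on the log2 scale.

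Among neuronal lists, thalamus genes leaned toward ICSI-F2 and newborn neuron and presynaptic genes toward control. Lhx9 (log2 fold change 0.18), Lef1 (0.22) and Tcf7l2 (0.11), transcription factor genes of the thalamus, passed when adjusted over the list alone, 3 of 15 genes (limma camera adjusted p = 0.00432; adjusted p = 0.363 with an estimated correlation), with a median of 0.063. Without the code letter G libraries the median was 0.057, about as large, and the call did not hold (limma camera adjusted p = 0.135). The newborn neuron list, with 12 of 17 genes below control, had a median log2 fold change of -0.0046 and included the microtubule genes Dcx (-0.08) and Tubb3 (-0.07) and also Mllt11 (-0.06), with an adjusted p of 0.0268 and an adjusted p of 0.516 with an estimated correlation in limma camera. That median moves with single libraries, and was 0.0034 without the code letter G libraries, where the call did not hold (limma camera adjusted p = 0.71). Of 30 synaptic vesicle genes 22 were below control, with Rab3a at -0.10 and Rims2 at 0.10 (adjusted p = 0.015 in limma camera; adjusted p = 0.744 with an estimated correlation), and the median was 0.021 without the code letter A libraries. Lists of cortical excitatory neurons (Rorb -0.13, Bcl11b -0.10), inhibitory neurons (Sp8 -0.33, Dlx2 -0.14), striatal neurons (Meis2 -0.11, Drd1 0.14), monoaminergic neurons (Tph2 0.31, Aldh1a1 0.23) and postsynaptic receptors (Grin1 -0.11, Grin2b -0.07) gave limma camera adjusted p of 0.375, 0.439, 0.288, 0.632 and 0.204.

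Processes showed small shifts. Of 76 cytosolic ribosomal protein genes 57 were above control, with a median log2 fold change of 0.03, and Rps24 (0.14), Rpl23 (0.13) and Rpl17 (0.13) passed when adjusted over the list alone (limma camera adjusted p = 2.61e-06; adjusted p = 0.516 with an estimated correlation). Of 23 hypoxia and glycolysis genes 19 were below control, among them Eno1 (-0.11), Gapdh (-0.09) and the mitophagy gene Bnip3 (-0.22), with an adjusted p of 1.61e-05 in limma camera and an adjusted p of 0.516 with an estimated correlation. Of 24 immediate early genes 19 were below control, with Jun at -0.22, Egr1 at -0.32 and Klf4 at -0.36, and 1 passed when adjusted over the list alone (limma camera adjusted p = 0.00432; adjusted p = 0.363 with an estimated correlation). The hypoxia and glycolysis call did not hold without the code letter A libraries (limma camera adjusted p = 0.418), where the median was -0.033, against -0.089 with all 8. With single libraries left out, limma camera with the preset correlation kept the newborn neuron call in 4 of 8 fits, the microglia, oligodendrocyte, synaptic vesicle and clustered protocadherin calls in 5 and the astrocyte and blood calls in 6. The other 6 called lists kept theirs in all 8. Newborn neurons lost it without control replicate 3 or 4 (adjusted p = 0.0838 and 0.0778) and without ICSI-F2 replicate 3 or 4 (0.212 and 0.0998). Their median was then further from 0, at -0.030, -0.030, -0.020 and -0.015, against -0.0046 with all 8 libraries. Microglia lost it without control replicate 3 (0.0677) and without ICSI-F2 replicate 3 or 4 (0.111 and 0.0998), at medians of 0.088, 0.093 and 0.067, against 0.091 with all 8. The oligodendrocyte call was lost without control replicate 1 (0.206) and without ICSI-F2 replicate 1 or 2 (0.0575 and 0.101), at medians of -0.026, -0.061 and -0.044, against -0.067. For synaptic vesicles it was lost without control replicate 1 or 2 (0.473 and 0.0662) and without ICSI-F2 replicate 2 (0.243), at medians of 0.0014, -0.020 and -0.0095, against -0.030. For protocadherins it was lost without control replicate 3 (0.107) and without ICSI-F2 replicate 1 or 4 (0.074 and 0.0918), at medians of -0.036, -0.039 and -0.033, about the -0.035 with all 8. The astrocyte call was lost without control replicate 1 (0.208) and without ICSI-F2 replicate 2 (0.315), at medians of -0.027 and -0.052, against -0.097. The blood call was lost without control replicate 4 (0.0816) and without ICSI-F2 replicate 4 (0.0998), at medians of 0.028 and 0.026, against 0.047. The other process lists did not pass in limma camera: nuclear genes of oxidative phosphorylation (Ndufa2 0.25, Cox6c 0.17, adjusted p = 0.0531), mitochondrially encoded genes (mt-Co1 -0.08, adjusted p = 0.18), cholesterol synthesis (Idi1 -0.22, adjusted p = 0.164), proliferation (Rrm2 -0.19, Plk1 -0.26, adjusted p = 0.342), heat shock and unfolded protein (Atf4 0.10, adjusted p = 0.566), glucocorticoid and circadian genes (Pdk4 -0.70, Nr1d1 -0.25, adjusted p = 0.566) and the interferon response (Irf7 -0.62, adjusted p = 0.806).

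Genes under epigenetic control are of interest in offspring of assisted reproduction. Imprinted genes split evenly, 28 above and 30 below control among 58 tested (limma camera adjusted p = 0.836), with Peg13 at -0.10, Cdkn1c at 0.17 and Kcnq1ot1 at 0.11 on the log2 scale. Clustered protocadherin genes, which code for adhesion proteins of single neurons, were below control in 33 of 55 cases, among them Pcdhgc3 (-0.11), Pcdhga9 (-0.19) and Pcdhgb5 (-0.19), with an adjusted p of 0.0245 in limma camera and an adjusted p of 0.363 with an estimated correlation. Without the code letter G libraries the median was -0.042 and the call did not hold (limma camera adjusted p = 0.143). These genes share exons within a cluster, so their counts are uncertain. Of 42 genes of DNA methylation and chromatin 28 were above control, led by the imprinting regulator Zfp57 (0.17, 169.7 ± 7.60 and 191.7 ± 13.1 CPM, SD, n = 4), Ezh2 (0.15) and Atrx (0.09), and the list did not pass (adjusted p = 0.0752 in limma camera). Replication-dependent histone genes (Hist1h1e -0.20, Hist1h4d -0.17, adjusted p = 0.142) and germline genes that depend on methylation (Tdrd1 -0.58, Brdt -0.23, adjusted p = 0.637) did not pass in limma camera. Adjusted over the list alone, 1 chromatin gene and 2 histone genes passed, and over all genes tested none did with the filter on low counts. With no filter Zfp57 and Hist1h1e passed in edgeR (adjusted p = 0.00566 and 0.0417). Genes linked to autism and intellectual disability (Grin2b -0.07, Cul3 -0.08) gave an adjusted p of 0.404 in limma camera.

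**Figure D3:**
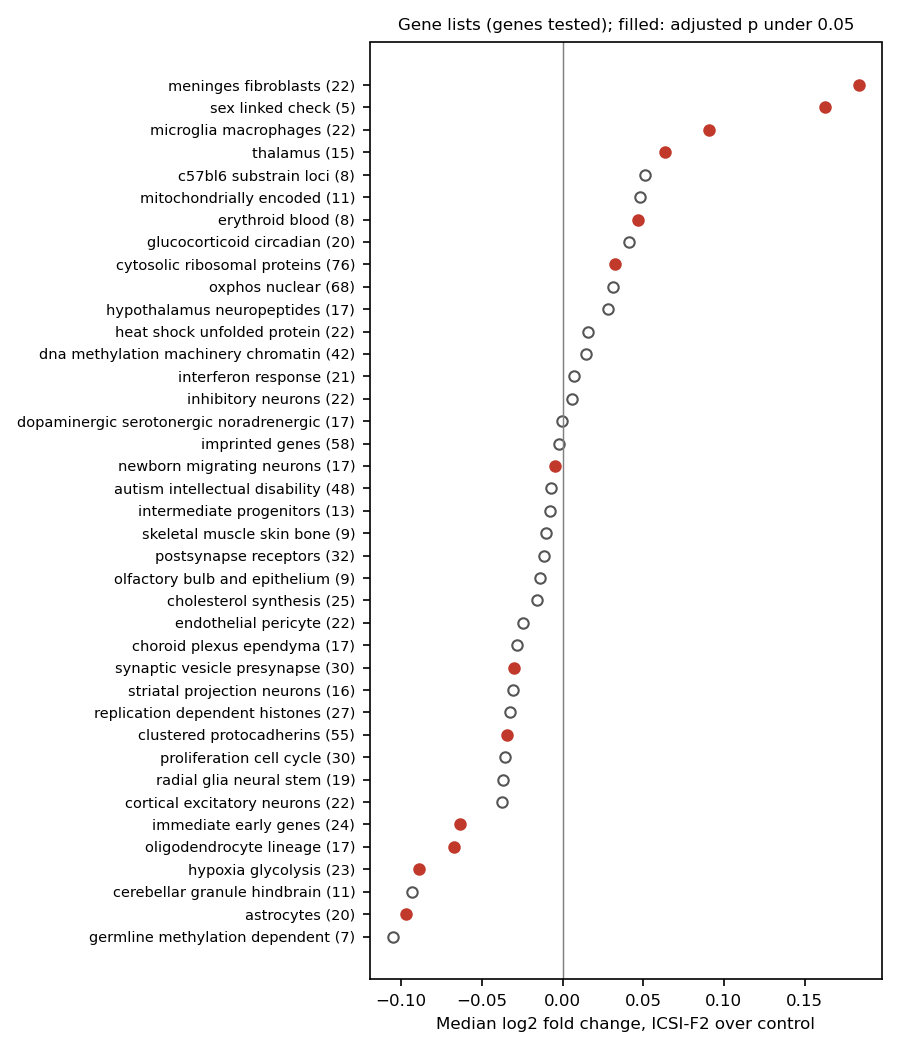
Median log2 fold change (ICSI-F2 over control, x axis) of the tested genes of each list, with the number of genes in brackets, and filled points for the 13 lists past the threshold in limma camera with a preset correlation. The meningeal list lies highest at 0.18 and the list of germline genes lowest at -0.11.

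Of 39 lists, 13 passed with the preset correlation, 6 toward ICSI-F2 and 7 toward control, and 0 passed in limma camera with an estimated correlation, where 4 had an unadjusted p under 0.05. The count was 0 in limma's fry, with 5 at an unadjusted p under 0.05, and 0 in the exact permutation test, with 2 under 0.05 and a smallest possible p of 0.0286. A list at that floor can pass after adjustment only if many other lists reach it too. Lists of other tissues and regions that did not pass in limma camera were choroid plexus (Prlr 0.13, adjusted p = 0.685), muscle, skin and bone (Neb 0.25, adjusted p = 0.836), endothelium and pericytes (Flt1 -0.20, adjusted p = 0.424), hindbrain and cerebellum (Hoxb3 -2.93, Slc6a5 -1.96, adjusted p = 0.288), hypothalamus (Gal -0.65, adjusted p = 0.851), olfactory bulb (Eomes -0.15, adjusted p = 0.288) and intermediate progenitors (Neurod4 0.72, adjusted p = 0.879). The 3 hindbrain genes Hoxb3, Slc6a5 and Pax2 changed sign without the code letter A libraries.

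All 8 libraries had the counts of male tissue, with 2 to 15 counts of Xist, 703 to 855 of Ddx3y, 899 to 1150 of Kdm5d, 733 to 1008 of Eif2s3y and 594 to 757 of Uty. Eif2s3y stood at 52.1 ± 5.06 CPM in control and 63.8 ± 2.40 CPM in ICSI-F2 brains (SD, n = 4) and did not pass in edgeR (adjusted p = 0.0954). It passed in edgeR with no filter (adjusted p = 0.000199), without control replicate 3 (adjusted p = 0.0249) and without control replicate 4 (adjusted p = 0.0407). The 5 tested genes of the sex list were all above control (limma camera adjusted p = 0.000135; adjusted p = 0.363 with an estimated correlation). Xist (log2 fold change 1.01, on few counts) and the Y-linked genes mark opposite sexes, so their rise together does not show a difference in sex. Nnt was counted 44 to 88 times per library in both groups, and the C57BL/6 substrain list gave an adjusted p of 0.273 in limma camera, with Crb1 at 0.31, Mmrn1 at 0.48 and Cyfip2 at -0.10 on the log2 scale. Wdfy1, also on that list, was uneven inside the groups, at 30.6 to 99.3 CPM in control and 67.0 to 104 CPM in ICSI-F2 libraries. Its log2 fold change was 0.20 (edgeR adjusted p = 0.949). None of the sex and substrain genes passed the edgeR test over all genes with all 8 libraries and the filter on low counts, where Eif2s3y, Ddx3y, Kdm5d, Crb1, Cyfip2 and Mmrn1 had an unadjusted p under 0.05.

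**Figure D4:**
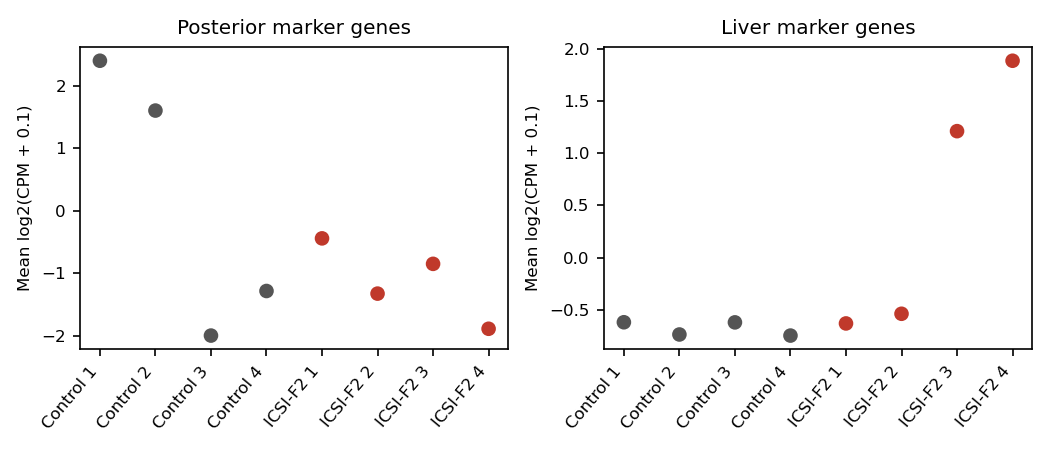
Mean log2(CPM + 0.1) of posterior marker genes (left) and of liver marker genes (right), y axes, in each control (grey) and ICSI-F2 (red) library. Control replicates 1 and 2 lie at 2.41 and 1.61 for posterior genes, and ICSI-F2 replicates 3 and 4 at 1.21 and 1.88 for liver genes, above the other 6 libraries in each case.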

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

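The tests of the Nnt allele, a chromosome segment, overlapping genes and a group difference in liver genes were chosen after their values were seen. The others were chosen before their results, but the posterior and liver marker lists were made after some of those genes had been seen. The score of the posterior group test includes Slc6a5, Hoxb3 and Pax2, which showed the pattern. Single libraries stood far from the other 3 of their group in 13 of 362 groups of values, where chance gives about 18.1. Prpf38b, a splicing factor gene, stood at 57.4 CPM in control replicate 1 and at 95 to 102 CPM in the other controls, against 65.2 to 72.4 CPM in ICSI-F2 libraries. Without control replicate 1 its log2 fold change was -0.51 (edgeR adjusted p = 9.77e-08), the smallest adjusted p of that fit, and without the code letter A libraries it was -0.53 (edgeR adjusted p = 6.76e-08), against -0.35 (edgeR adjusted p = 0.739) with all 8 libraries. Pax2, a transcription factor gene of the hindbrain, stood at 6.40 CPM in ICSI-F2 replicate 1 and at 0.304 to 0.843 CPM in the other ICSI-F2 libraries. Control replicate 1 also stood apart in Calb1 (33.7 CPM), control replicate 3 in Ogn (10.9 CPM) and Pcdhgb5 (28.2 CPM), and control replicate 4 in Plk1 (8.52 CPM). ICSI-F2 replicate 2 stood apart in Pcdhgc3 (105 CPM) and the Y-linked Kdm5d (82.6 CPM), and ICSI-F2 replicate 4 in Drd1 (17.2 CPM). Relative to the control mean on the log2 scale, the chromatin list stood at -0.0165 in control replicate 1, the inhibitory neuron list at -0.0732 in ICSI-F2 replicate 1 and the glucocorticoid and circadian list at -0.0486 in control replicate 3. ICSI-F2 replicate 1 had 16348777 counts, and the others of its group 12968175 to 13156327.

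The group comparison gave 1 gene, and 6 of the 35 splits of the 8 libraries into 4 and 4, the real one included, gave at least as many, so chance is not excluded for that count. The highest other split gave 58 genes, several times the real count, which points to a structure of the samples other than the groups. It set control replicates 1 and 2 and ICSI-F2 replicates 1 and 3, the 4 libraries with the highest scores of posterior marker genes (2.41, 1.61, -0.44 and -0.85), against the others. Of its 58 genes 37 were higher in those 4 libraries. Only 11 of the 26 posterior markers were tested there, and 1, En1, passed (log2 fold change 0.72). Transcription factor genes outside that list passed too, some higher (Irx2 0.54, Ebf2 0.46, Lhx1 0.40) and some lower (Tbr1 -0.18, Neurod6 -0.21, Dlx5 -0.38). These were picked after their values were seen. Whether tissue content explains that split was not tested further. The split of code letters A and G against D and F gave 15 genes, and that of A and F against D and G gave 3. For the 13 gene lists past the threshold with the preset correlation, 12 of the 35 splits gave as many, with up to 21 in another split, and the split of A and F against D and G gave 13. With the code letter as a random block, limma still called 1 gene, Tmem267.

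Tmem267 was higher in ICSI-F2 brains, and a difference in the Nnt allele as its cause is argued against by the log2 fold change of Nnt, -0.11, with an interval inside -1 to 1. The overlapping genes were themselves counted at no more than 2.30 CPM together in an ICSI-F2 library, where Tmem267 gained at least 7.18 CPM. Reads wrongly counted as Tmem267 would be missing from that sum, and the strand setting is not known. The test therefore cannot decide whether reads of overlapping genes contributed. Different hindbrain or meninges content as the whole cause is argued against by the log2 fold change of 0.96 (adjusted p = 3.41e-05 in edgeR) that Tmem267 had with the scores of both lists as covariates, a fit that called 15 genes. Ccl28 and 3110070M22Rik did not pass with all 8 libraries and the filter on low counts, and neither overlapping genes nor tissue content was tested for them. A difference carried by a chromosome segment, such as an inherited variant, may apply but cannot be told apart from other causes: 2 of the 6 nearest genes had p under 0.05 in the same direction, as for 2.37% of other genes, but those 2 had been seen before the test was chosen, and none of the remaining 4 did. An effect of the ICSI ancestry itself stays open and was not tested apart from the families used.

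Hox genes, Slc6a5 and Pax2 were high in control replicates 1 and 2, and a larger share of hindbrain or spinal cord in that tissue may explain this. The posterior marker genes other than Hoxb3, Slc6a5 and Pax2, 23 in all, moved together within the groups, with a median pairwise correlation of 0.824 across genes' library values. Most of these are Hox genes too, so the correlation in part restates the pattern. A difference between ICSI-F2 and control is argued against by the controls themselves, since control replicates 3 and 4 had scores of -1.997 and -1.28, within or below the ICSI-F2 scores of -1.89 to -0.44 (exact permutation test, two-sided, p = 0.371). The most abundant Hox genes there were Hoxb5, at 17.7 CPM in control replicate 1, and Hoxb3, at 7.69 CPM in control replicate 2.

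Liver transcripts were high in ICSI-F2 replicates 3 and 4, and liver tissue or its RNA carried into those libraries may explain this. Of 18 detected liver markers other than the 5 that showed the pattern, 11 (61.1%) were higher in both libraries than in each of the other 6, where chance gives 3.57%, with Fga at 2.22 and 3.42 CPM and Ahsg at 1.99 and 6.16 CPM. Brain tissue also expresses several of these markers, among them Ttr, at 271.7 to 443.1 CPM, and Trf, at 9.05 to 10.8 CPM in the other 6 libraries. A difference shared by the ICSI-F2 group is argued against, since it needs ICSI-F2 replicates 1 and 2 to be raised too. Their score was 0.0963 above the control mean on the log2 scale, at -0.63 and -0.54, with controls at -0.75 to -0.62 and ICSI-F2 replicates 3 and 4 at 1.21 and 1.88. A difference in the code letter G animals other than carried-over RNA was not tested and stays open.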

How the results depend on the processing

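The runs without the code letter A or G libraries and the exact permutation test were chosen after the data were seen. Tmem267 passed in all 19 alternative gene fits, at log2 fold changes of 0.91 to 1.11 and adjusted p of 1.04e-21 to 0.00528. The count of differing genes was 50 (35 higher, 15 lower) with no filter, 13 (8 and 5) with 1 surrogate variable, 2 (2 and 0) with DESeq2, 3 (3 and 0) with counts summed per code letter, 4 (4 and 0) at an adjusted p of 0.10 and 6 (4 and 2) without letter A. With 1 library left out it was 1 to 9 genes, with 1 to 9 higher and 0 to 2 lower, at 9 without control replicate 3, 4 without control replicate 1 and 3 without control replicate 4. Of the sex and substrain genes 1, Eif2s3y, passed with no filter, and it also passed without control replicate 3 or 4. Slc1a2 and Sp8 passed with no filter and Bcl11b with 1 surrogate variable. With the hindbrain and meninges scores as covariates, a fit made for the test of Tmem267, the count was 15. The 13 lists became 0 with an estimated correlation, with fry and with the exact permutation test, and 20 without letter A. The exact permutation test has a smallest possible p of 0.0286. It could hardly pass after adjustment over 39 lists, so its count of 0 does not speak against the calls. The cause was not tested. The filter changes how many genes are fitted, 24101 against 15565. With no filter the adjusted p of Tmem267 went from 2.04e-05 to 1.04e-21 at about the same log2 fold change, 1.04. That fit also called Fgg and Pzp (edgeR adjusted p = 0.00711 and 0.0177), liver genes raised only in ICSI-F2 replicates 3 and 4. A call with no filter alone therefore does not show a difference shared by the group. Depth limits genes of few counts most. The whole 95% interval lay within 1.5-fold of no change for 99.4% of genes at 10 CPM or more and for 83.8% of all tested genes.

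Of 2618 gene values, 23 in 14 genes had the opposite sign, none of them called in either setting, and 34 passed where they had not before. Without letter A the log2 fold changes turned to 0.021 (Slc32a1), 2.78 (Hoxb3), 1.19 (Slc6a5), 0.037 (Gng13), 0.081 (Agt), 0.019 (Paip1), -0.24 (Wdfy1) and 1.81 (Pax2). Without letter G they were 0.044 (Gng13), -0.0097 (Slc4a1), -0.056 (Mybpc1), -0.11 (Wdfy1) and -0.017 (Col1a1). Hmgcs1 turned to 0.0050 with total library size, and with 1 surrogate variable Hmgcs1 was 0.0022, Wdfy1 -0.021 and Pax2 0.63. With 1 library left out, Cdhr1 ran from -0.63 to 0.011, Paip1 from -0.038 to 0.0060, Hmgcs1 from -0.015 to 0.0055, Nnt from -0.23 to 0.045 and Wdfy1 from -0.062 to 0.38.

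Of 546 list values, 54 in 23 lists had the opposite direction in the test, 6 of them called in either setting, 65 lost their call and 30 gained one. Without letter A camera's direction turned for lists whose medians were then radial glia 0.0090, proliferation 0.047, intermediate progenitors 0.047, hindbrain 0.22 (now past the threshold), olfactory bulb 0.031, astrocytes 0.013, oligodendrocyte lineage 0.031, choroid plexus -0.016, synaptic vesicle 0.021 and substrain loci 0.033, and the medians of choroid plexus and substrain loci kept their sign. Without letter G they were proliferation 0.070 (now past the threshold), intermediate progenitors 0.040, hypothalamus -0.076, choroid plexus 0.038, meninges -0.018, muscle and skin 0.018, heat shock 0.0054, cholesterol synthesis -0.016, imprinted genes -0.0088 and histones 0.018, and those of heat shock, cholesterol synthesis and imprinted genes kept their sign. The exact permutation test, on list means, went against camera for intermediate progenitors (median -0.0075), monoaminergic neurons (-6.7e-05), hypothalamus (0.028) and glucocorticoid and circadian genes (0.041), and total library size turned camera's direction for hypothalamus (0.039), where the median kept its sign. With 1 library left out, the medians of lists whose direction turned in at least 1 such fit ran from -0.081 to 0.011 for proliferation, -0.041 to 0.025 for intermediate progenitors, -0.067 to 0.034 for cortical neurons, -0.060 to 0.091 for monoaminergic neurons, -0.24 to -0.0060 for hindbrain, -0.0091 to 0.048 for hypothalamus, -0.12 to 0.028 for olfactory bulb and -0.046 to 0.017 for endothelium. They ran from -0.13 to 0.053 for choroid plexus, -0.059 to 0.023 for muscle and skin, -0.026 to 0.038 for heat shock, -0.11 to 0.078 for interferon, -0.039 to -0.0089 for cholesterol synthesis, -0.012 to 0.011 for imprinted genes and -0.17 to 0.024 for germline genes. In 5 lists camera's direction differed from the sign of the median, and in 7 the median and the mean differed in sign.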

Other observations

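The genes named here were chosen after their values were seen. Several genes stood at separate levels in single libraries or code letters. Wdfy1 is an endosomal adaptor gene on the substrain list. It was at 30.6, 65.3, 97.6 and 99.3 CPM in control replicates 1 to 4 and at 67.9, 67.0, 104 and 96.6 CPM in ICSI-F2 replicates 1 to 4. A430106G13Rik was at 2.45 CPM in control replicate 1 and at 13.5 to 16.9 CPM in the other 7 libraries. Capn11, a calpain gene, was at 5.85 and 3.76 CPM in control replicates 3 and 4 and at 0.133 to 0.537 CPM in the other 6. Without the code letter A libraries it was called lower in ICSI-F2 (log2 fold change -3.79, edgeR adjusted p = 6.88e-09). Gh, the growth hormone gene of the pituitary, was at 0.795, 1.26 and 0.252 CPM in control replicates 1 to 3 and had 0 counts in the other 5. With no filter on low counts it was called lower in ICSI-F2 (log2 fold change -6.11, edgeR adjusted p = 0.000184).

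Of the sex chromosome genes, 3 singled out by their values did not pass in edgeR with all 8 libraries and the filter on low counts, and each passed in at least 1 other setting. Mid1, a ubiquitin ligase gene on chromosome X from 169685199 to 170005736, stood at 10.4 ± 2.63 CPM in control and 20.1 ± 3.81 CPM in ICSI-F2 brains (SD, n = 4), a log2 fold change of 0.94 (edgeR adjusted p = 0.427), with all 4 ICSI-F2 libraries above all 4 controls. It passed in 6 settings, with adjusted p of 1.02e-05 in DESeq2, 4.4e-14 with no filter, 0.0074 with counts summed per code letter, 0.0105 with 1 surrogate variable, 5.37e-05 without control replicate 1 and 0.00241 without the code letter A libraries, the others in edgeR. The next gene, Gm21887, gave a log2 fold change of 1.85 (edgeR adjusted p = 0.608) and passed with 1 surrogate variable (2.56, edgeR adjusted p = 0.00273), and Gm47283 on chromosome Y gave 0.91 (edgeR adjusted p = 0.658) and passed with counts summed per code letter (0.92, edgeR adjusted p = 0.0286). How reads were shared between genes of chromosomes X and Y was not tested. The counts of these 3 genes are therefore uncertain, and they may not be separate results.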
